A study of Mus musculus with 18 samples.

How the data were processed

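Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on limb buds of wild-type CD1 mouse embryos, an outbred strain. Tissue was crosslinked with formaldehyde, and sonicated chromatin was pulled down with an antibody, per the labels' protocols. The series holds 18 samples, each labelled with a limb, a stage and an antibody or input. They cover 6 histone marks and inputs in forelimb buds at e10.5 and hindlimb buds at e11.0, Pitx1 with an input in hindlimb buds at e11.5, and Tbx5 with an input in forelimb buds at e10.5. Peak lists of 2 of these samples were analysed here, the Pitx1 sample and the Tbx5 sample, each labelled as paired-end and made with a homemade antibody. The histone mark and input samples are not analysed here.

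The deposited lists give the position of the highest point of each peak, called the summit, on genome build mm10. Per the submitters' processing notes, the tools included Bowtie 1.1.2, Bowtie2 2.2.6, MACS2 2.1.1.20160309 and HOMER, with no role or order given for any of them. The names of the deposited peaks contain the word macs2. The deposited score of each summit was read as the −log10 of the peak's q-value, which is what MACS2 writes to summit files. The lowest scores, 1.31 for Pitx1 and 1.42 for Tbx5, lie just above 1.30, the −log10 of 0.05. The control library given to the peak caller, the numbers of reads and any filter applied after peak calling are not given in the sources used here. Each deposited list belongs to 1 sample, and nothing in the sources used here says whether reads of several libraries were pooled. The names of the Tbx5 peaks contain "rep2", and the authors marked the second Pitx1 list described below with a suffix that contains "rep2" as well. Whether a further library of either factor was used is not given in the sources used here.

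A second deposited Pitx1 list of 17783 summits holds a subset of the longer list. Each of its summits has the name and position of a summit in the longer list, with the score cut to 2 decimals. It carries a further deposited score between 50.01 and 2501.27 and a pair of distances in bp, none of which is explained in the sources used here. The longer Pitx1 list was used for the main results and the subset as an alternative.

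Peaks are numbered in genome order within each list, and numbers are missing from both lists. The highest number is 70575 for Pitx1, of which 77.8% are present, and 17019 for Tbx5, of which 60.4% are present. The share of numbers present on a chromosome was taken as the share of called peaks left in the deposited list. Read depth is unknown, so exact Clopper-Pearson 95% intervals on shares of summits cover the counting of summits within a list and no other error. With 1 sample per factor there is no replicate error for any value. Factor, limb, stage and antibody differ together between the lists, so every test compares these lists and not the tissues.

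Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 represents, with 21887 protein-coding genes. The table gives the start and end of each gene without strand, exons or sequence. Measures planned on transcription start sites were therefore replaced by measures on gene ends, counting both ends of each gene. A summit was called close to a gene end when it lay within 1 kb of either end of a protein-coding gene. Each summit was assigned to the nearest protein-coding gene, a summit inside a gene being at distance 0, up to 100 kb. The domain of a gene is the stretch of sequence that would be assigned to it. Exonic, intronic and untranslated positions are not given here, and the planned counts of sequence motifs were not run.

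A Tbx5 summit was called shared when a Pitx1 summit lay within 200 bp. The number of shared summits was compared with 1000 random placements of the Tbx5 summits, each keeping the chromosome and the class of distance to gene ends, inside or outside genes, in a one-sided permutation test. The smallest p these placements can give is 0.001. For the number of genes with summits of both factors, a comparison added after the data were examined, Tbx5 counts were permuted 1000 times among genes within 50 classes of domain length, with all summits and without the shared ones. The trend of sharing across 5 groups of the score was tested by 100000 permutations, two-sided, with a smallest p of 2e-05.

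For gene lists, the mean number of summits per gene was compared with 10000 random lists of as many genes, drawn from the same 10 classes of domain length. The test is a two-sided permutation test with a smallest p of 0.0002, adjusted by the Benjamini-Hochberg method over the 14 lists with at least 5 genes. The difference between the factors was tested on the log2 of the ratio of observed to random for Pitx1 over that for Tbx5, with a pseudocount of 0.5 summits, and the share of a list's Pitx1 summits that was shared with Tbx5 was tested in the same way. Genes are not replicates, and neighbouring genes such as those of a Hox cluster are not independent, so p-values of lists with neighbours are too small. The 15 lists, with 265 genes in all, are genes associated with the hindlimb, genes associated with the forelimb, limb transcription factors, limb signalling, posterior Hoxa and Hoxd genes, chondrogenesis, muscle, ectoderm with the apical ridge, endothelium, blood, cardiac, pituitary, neuronal, hepatocyte and ubiquitous genes. All 265 symbols were found in the annotation.

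The gene lists, the tests, the choice of named genes and most alternatives were fixed before the data were examined. The replacements for start sites and the alternatives described as added were chosen after. Named genes are the 10 with the highest-scoring summit and the 10 with the most summits for each factor, and the 10 with the shared site that ranks best by the lower of its ranks, each rank taken as a percentage of its list. Of each gene list they are the 4 members with the most summits of each factor and up to 2 with none, and in addition Pitx1, Tbx4 and Tbx5. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

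The procedures were tested on simulated data over the 21887 genes. Random lists of 25 genes whose Pitx1 summits were tripled were called in 17 of 20 runs, and those with tripled Tbx5 summits in 13 of 20. Lists left as deposited were called in 5 of 100 runs for each factor, at an unadjusted threshold of 0.05. Random placements passed the overlap test in 0 of 20 runs, and planting sites in 20% of the Tbx5 list gave a shared share of 21.0%. The number of genes with both factors exceeded all permutations in 0 of 10 runs with summits placed by domain length alone. The runs without planted sites and these runs followed the same rules as the nulls they were set against, with 100 draws each. They therefore check the calculation and cannot show whether other features of real lists give an excess. Alternatives covered the score threshold, the second Pitx1 list, lists of equal length, the distance that counts as shared, the way sites were placed, the assignment to genes and the measure per gene. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9.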

Results

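The study addressed how forelimb and hindlimb buds, which use many of the same genes, differ in the gene networks that shape them. Pitx1, a homeodomain transcription factor of the hindlimb bud, was mapped in hindlimbs at e11.5, and Tbx5, a T-box transcription factor needed for forelimb outgrowth, in forelimbs at e10.5. Each map was deposited as 1 sample with no separate replicate, so no value below has a replicate error. The Pitx1 list held 54941 summits, with a median score of 7.07 and quartiles of 3.83 and 15.1 in the authors' −log10 q. The Tbx5 list held 10273 summits, with a median of 8.29 and quartiles of 5.07 and 18.6. Because read depth is unknown, the difference in list length cannot be read as a difference in binding.

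Most binding sites of both factors lay away from gene ends. Of the Pitx1 summits, 13.5% (95% interval 13.2 to 13.7) were within 1 kb of either end of a protein-coding gene, and of the Tbx5 summits 7.42% (6.92 to 7.94). These stretches make up 2.94% of the genome, so the shares were 4.57 and 2.52 times that of the genome. Inside genes and over 1 kb from their ends lay 42.4% of Pitx1 and 42.6% of Tbx5 summits, against 36.7% of the genome. Regions over 100 kb from any protein-coding gene held 18.5% of Pitx1 and 22.9% of Tbx5 summits, against 29.2% of the genome. The share near gene ends was 10.3% (9.76 to 10.95) for the 10273 Pitx1 summits with the highest scores and 8.80% (8.39 to 9.23) for the second Pitx1 list.

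The strongest Pitx1 summits lay at genes of varied function. The highest score near a gene, 769, was at chromosome 19 position 5366840, inside Banf1, which encodes a chromatin-binding protein of the nuclear envelope. Scores of 684 at chromosome 5 position 142818902 inside Tnrc18 and 590 at chromosome 5 position 134456897, 0.03 kb outside Gtf2ird1, followed. Others among the 10 highest were inside Lgi1 (566), Glis1 (553), Dclk1 (550), Cpa5 (545), Spock1 (538) and Pnkd (534), and 6.11 kb outside Natd1 (532). By number, Auts2 held 109 Pitx1 summits, Lrmda 88, Tenm3 83, Mecom 81, Macrod2 73, Zfhx3 72, Rad51b 72, Wwox 70, Robo1 70 and Pard3b 69. These are long genes, with assignment domains between 651 kb for Rad51b and 2087 kb for Macrod2.

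The strongest Tbx5 summit near a gene scored 1477 and lay at chromosome 15 position 103305430, 2.80 kb outside Gpr84. Hsd11b2, which encodes an enzyme that inactivates glucocorticoids, held a summit with a score of 1252 at chromosome 8 position 105519818. A summit with a score of 886 at chromosome 6 position 4557335 lay 15.8 kb outside Col1a2, a type I collagen gene. Zfp608 held a summit with a score of 800 at chromosome 18 position 54978660. Others among the highest were inside Crocc2 (665), Pknox2 (516), Nln (486) and Iqca (481), and 19.2 kb outside Mrpl23 (542). Lrmda held the most Tbx5 summits, 53, followed by Mecom with 22, Tenm4 with 21, Auts2 with 20, Macrod2 with 18, Sox6 and Bcas3 with 17 each, Foxp1 and Gpc6 with 16 each and Creb5 with 15. Their assignment domains were also long, between 479 kb for Bcas3 and 2087 kb for Macrod2.

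Pitx1 in the hindlimb and Tbx5 in the forelimb occupied many of the same sites. Of the 10273 Tbx5 summits, 4062 had a Pitx1 summit within 200 bp, which is 39.5% (95% interval 38.6 to 40.5) of the Tbx5 list and 7.39% of the Pitx1 list. Random placements gave a mean of 117.4 shared summits and at most 169, so the observed number was 34.6 times the random mean (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The median distance from a Tbx5 summit to the nearest Pitx1 summit was 540 bp, against 23112 bp for a random placement, and shared pairs were a median of 60 bp apart. Among Tbx5 summits over 100 kb from any protein-coding gene, 1021 of 2355, or 43.4% (41.3 to 45.4), were shared. Cutting the Pitx1 list to the 10273 summits with the highest scores lowered the shared share to 17.8%. The ratio to random rose to 83.4, and with the second Pitx1 list the values were 23.2% and 64.8. Moving the Tbx5 summits by 5 to 20 kb, which keeps their neighbourhood, gave a mean of 205.4 shared summits and a lower ratio of 19.8. The ratio was 49.8 when pairs within 100 bp counted as shared, 17.97 within 500 bp and 10.98 within 1000 bp. Uniform placement gave 44.1, and the higher-scoring part of each list 65.2.

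**Figure D1:**
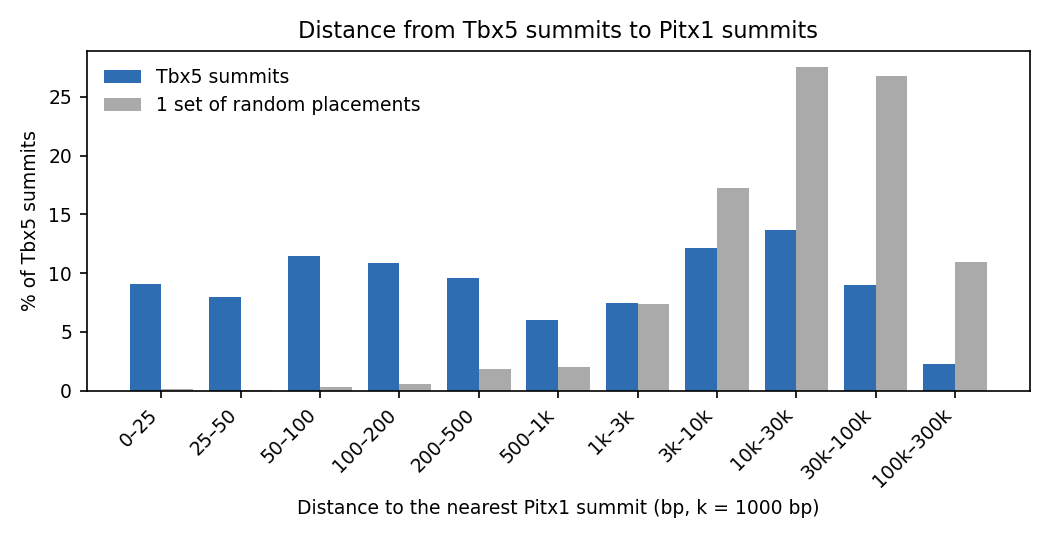
Percentage of the 10273 Tbx5 summits (vertical axis) by distance in bp to the nearest Pitx1 summit (horizontal axis, unequal classes), with 1 set of random placements in grey. Distances under 25 bp held 9.09% of Tbx5 summits and 0.107% of the random placements.

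The shared sites with the best ranks in both lists lay at genes of varied function. The first of them was inside Pknox2, which encodes a homeodomain protein that partners Pbx proteins, with a Tbx5 summit at chromosome 9 position 37030477 (score 516) and a Pitx1 summit 89 bp away (score 358). Zbtb16, a zinc finger gene needed for hindlimb skeletal patterning, held a Tbx5 summit at chromosome 9 position 48823153 (score 296) and a Pitx1 summit 114 bp away (score 484). Inside Hoxa9 a Tbx5 summit at chromosome 6 position 52226296 (score 220) lay 156 bp from a Pitx1 summit with a score of 510. The site outside Col1a2 was also shared, with the Pitx1 summit 39 bp away at a score of 175. The other shared sites of this rank were inside Msrb3, Mecom, Pakap and Dnm3, 26.4 kb outside Gm38821 and 5.83 kb outside Slc38a6. Their Tbx5 scores lay between 206 for Dnm3 and 253 for Mecom.

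Sharing rose with the strength of the peak in both lists. In 5 groups of summits from the lowest to the highest scores, the shared share of Tbx5 summits was 29.3%, 29.7%, 37.5%, 44.4% and 56.8%. For Pitx1 summits it was 2.95%, 3.77%, 5.06%, 7.98% and 17.4%. The top and bottom groups differed by 27.5 percentage points for Tbx5 and 14.4 for Pitx1 (two-sided permutation p = 2e-05 for each trend, the smallest that the permutations can give). Summits are not replicates, and the p-values describe these lists.

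**Figure D2:**
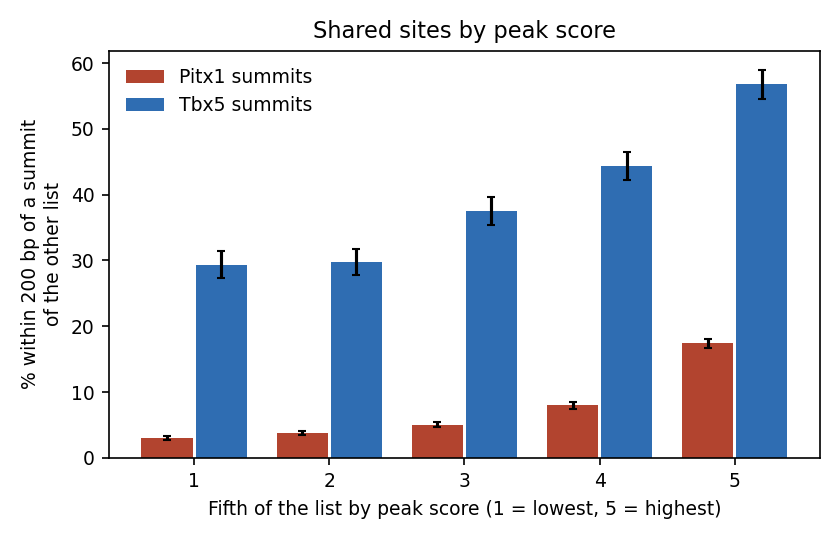
Percentage of summits within 200 bp of a summit of the other list (vertical axis) in 5 groups of the authors' score from lowest to highest (horizontal axis) for Pitx1 and Tbx5 summits, with exact 95% intervals as error bars. The highest bar is the top group of Tbx5 summits at 56.8%, and the lowest is the bottom group of Pitx1 summits at 2.95%.

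The sites of both factors often fell to the same genes. Of 21887 protein-coding genes, 11933 (54.5%) had a Pitx1 summit assigned and 4085 (18.7%) a Tbx5 summit. Both were assigned to 3672 genes, Pitx1 alone to 8261, Tbx5 alone to 413 and neither to 9541. Permuting the Tbx5 counts among genes of like domain length gave a mean of 2886 genes with both and at most 2976 in 1000 permutations, so the observed number was 1.27 times the mean. Part of this restates the shared sites. Leaving the shared summits out of both lists gave 2700 genes with both, against a mean of 2226 and at most 2288, or 1.21 times. Only summits with a partner within 200 bp were left out. Of all Tbx5 summits, 9.63% lay 200 to 500 bp from the nearest Pitx1 summit, against 1.84% of random placements. Another 5.996% lay 500 to 1000 bp away, against 2.03%. The ratio of 1.21 therefore cannot separate a choice of the same genes from sites that lie close together. The permutations also matched genes on domain length alone. Families described below, such as odorant receptors, hold few summits of either factor and were mixed with other genes. Neither the ratio of 1.27 nor that of 1.21 can separate a choice of the same genes from this mixing. With all summits, the numbers of summits per gene had a Spearman correlation of 0.494 across genes, which are not independent replicates, against a mean of 0.248 and at most 0.266 in the permutations.

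Genes known for hindlimb identity were examined to ask how much Pitx1 binding they receive. All 7 had Pitx1 summits, 94 in all, a mean of 13.4 per gene (SD 6.21 over genes) against 2.63 for random lists, or 5.10 times (permutation test, adjusted p = 0.00728). The gene Pitx1 itself and Tbx4, the T-box gene of the hindlimb, held 19 Pitx1 summits each, and Isl1, which acts in hindlimb initiation, held 15. The strongest Pitx1 summit assigned to Tbx4 had a score of 276, rank 143 in the list, and lay at chromosome 11 position 85876356, 10.01 kb outside the gene (85886367 to 85916097). The strongest assigned to Pitx1 (chromosome 13, 55825044 to 55836190) scored 61.9 and lay 63.0 kb outside it at position 55899207. Counting the share of genes with a summit in place of the mean, the hindlimb list gave 1.72 times random. Its adjusted permutation p was 0.0567, in a range of 0.0004 to 0.0567 over 10 alternatives. All 7 genes had a summit, so this measure could go no higher for the list.

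Tbx5 summits in the forelimb were about as frequent at the hindlimb genes as in random lists. Only Tbx4 of the 7 had any, namely 3, of which the highest scored 15.4, and 1 of its 19 Pitx1 summits was shared. The mean of 0.429 per gene was 0.904 times that of random lists (permutation test, adjusted p = 1). The Pitx1 ratio exceeded the Tbx5 ratio by 2.45 on the log2 scale, and this difference did not pass the test (permutation p = 0.0544, adjusted p = 0.381). The Tbx5 ratio rested on 3 summits and rose above 1 under 5 of the alternatives, reaching 3.69 when summits were assigned within 20 kb. In that setting the Pitx1 ratio was 12.6 and the log2 difference 2.14 (permutation p = 0.0444, adjusted p = 0.311, in a range of 0.137 to 0.704 over 10 alternatives).

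Genes associated with the forelimb carried sites of both factors. Tbx5 held 5 Tbx5 summits, the highest with scores of 87.5 at chromosome 5 position 119827538 and 69.8 at position 119796634, both inside the gene (119796514 to 119885220). It also held 23 Pitx1 summits in the hindlimb, the highest with a score of 60.8 at position 119848037. Of these 23, 2 were in the second Pitx1 list, which holds 32.4% of the longer list. The second list keeps few low-scoring summits, from 5.35% in the lowest of 10 score classes to 93.7% in the highest. The next highest of the 23 scored 16.6, so the 32.4% is not a like comparison. The Hox genes of this list are active in anterior parts of the body axis. Hoxc4 held 13 Pitx1 and 3 Tbx5 summits, Hoxc6 held 12 and 2, and Hoxc5 held 3 and 1. The means over the 4 genes were 12.75 Pitx1 summits, 4.49 times random, and 2.75 Tbx5 summits, 5.32 times random, and a list of 4 genes was too short to be tested.

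Both factors bound heavily around the transcription factors shared by both limbs. Of 34 such genes, 33 had Pitx1 summits and 26 Tbx5 summits. The Pitx1 mean was 14.4 per gene (SD 8.52), 3.67 times random (permutation test, adjusted p = 0.000933), and the Tbx5 mean was 3.35 (SD 2.91), 4.54 times random (adjusted p = 0.0014). Hand2, which sets the posterior side of the bud, held 34 Pitx1 and 3 Tbx5 summits. Meis1, a marker of the proximal limb, held 30 and 10, and Prrx1, a gene of limb mesenchyme, 30 and 6. Meis2 held 24 and 9, Gli3, a mediator of hedgehog signalling, 23 and 8, and Hes1 19 and 9. Gli1 (3 Pitx1 summits) and Msx2 (11) had no Tbx5 summit, and Pbx2 had none of either factor.

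Genes of limb signalling followed with smaller ratios. All 25 had Pitx1 summits and 20 had Tbx5 summits, with a Pitx1 mean of 10.7 (SD 7.88), 2.24 times random (permutation test, adjusted p = 0.0063), and a Tbx5 mean of 2.16 (SD 2.41), 2.36 times random (adjusted p = 0.0392). Rarb, a retinoic acid receptor, held 31 Pitx1 and 11 Tbx5 summits. Fgfr2, a fibroblast growth factor receptor, held 26 and 4, and 4 of its Pitx1 summits were shared. Ptch1, the hedgehog receptor, held 26 and 1, Bmp7 18 and 2, Hhip 15 and 5, and Dusp6, a target and inhibitor of fibroblast growth factor signalling, 12 and 6. Shh (3 Pitx1 summits) and Grem1 (1) had no Tbx5 summit assigned, and a limb enhancer of Shh known to lie far from the gene is outside the 100 kb used. With the higher-scoring part of each list, the Tbx5 call ended at 2.40 times random and an adjusted p of 0.0756, in a range of 0.000933 to 0.0756 over 8 alternatives.

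The posterior Hoxa and Hoxd genes, which pattern the limb along its length, held more summits of both factors than random lists. All 9 had Pitx1 summits and 4 had Tbx5 summits. Their domains are short, and the Pitx1 mean of 5.22 (SD 3.93) was 11.01 times random (permutation test, adjusted p = 0.000933), while the Tbx5 mean of 0.778 (SD 1.09) was 14.6 times random (adjusted p = 0.0014). Hoxa13 held 15 Pitx1 summits and no Tbx5 summit, and Hoxd10 held 7 and none. Hoxd9 held 5 and 2, Hoxa10 4 and 1, Hoxa9 3 and 3, Hoxd11 3 and 1, and Hoxa11 4 and none. The genes lie in 2 clusters of neighbours, so these p-values are too small. The excess was not particular to the genes of this list. Among the gene families described below, Hoxb, which has no gene in the list, also held more summits of both factors than random lists. Hoxa did too, but it includes Hoxa9, Hoxa10, Hoxa11 and Hoxa13 of this list and partly restates the same summits.

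Chondrogenesis genes, which lay down the cartilage of the limb skeleton, also held more summits of both factors than random lists. Of 22 genes, 20 had Pitx1 summits and 14 had Tbx5 summits. The Pitx1 mean was 14 (SD 16.9), 3.16 times random (permutation test, adjusted p = 0.000933), and the Tbx5 mean 3.09 (SD 4.73), 3.62 times random (adjusted p = 0.0149). Sox5 and Sox6, partners of Sox9 in cartilage, held 59 and 52 Pitx1 summits and 12 and 17 Tbx5 summits, and 11 of the Pitx1 summits at Sox6 were shared. Trps1 held 39 and 9, and Bmpr1b 31 and 10. Col2a1, which encodes the main collagen of cartilage, held 8 Pitx1 summits and no Tbx5 summit, in a domain of 48.8 kb against 1154 kb for Sox5. Acan and Snorc had none of either factor. Counting the share of genes with a summit in place of the mean, the Pitx1 ratio was 1.32 (permutation test, adjusted p = 0.0397).

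**Figure D3:**
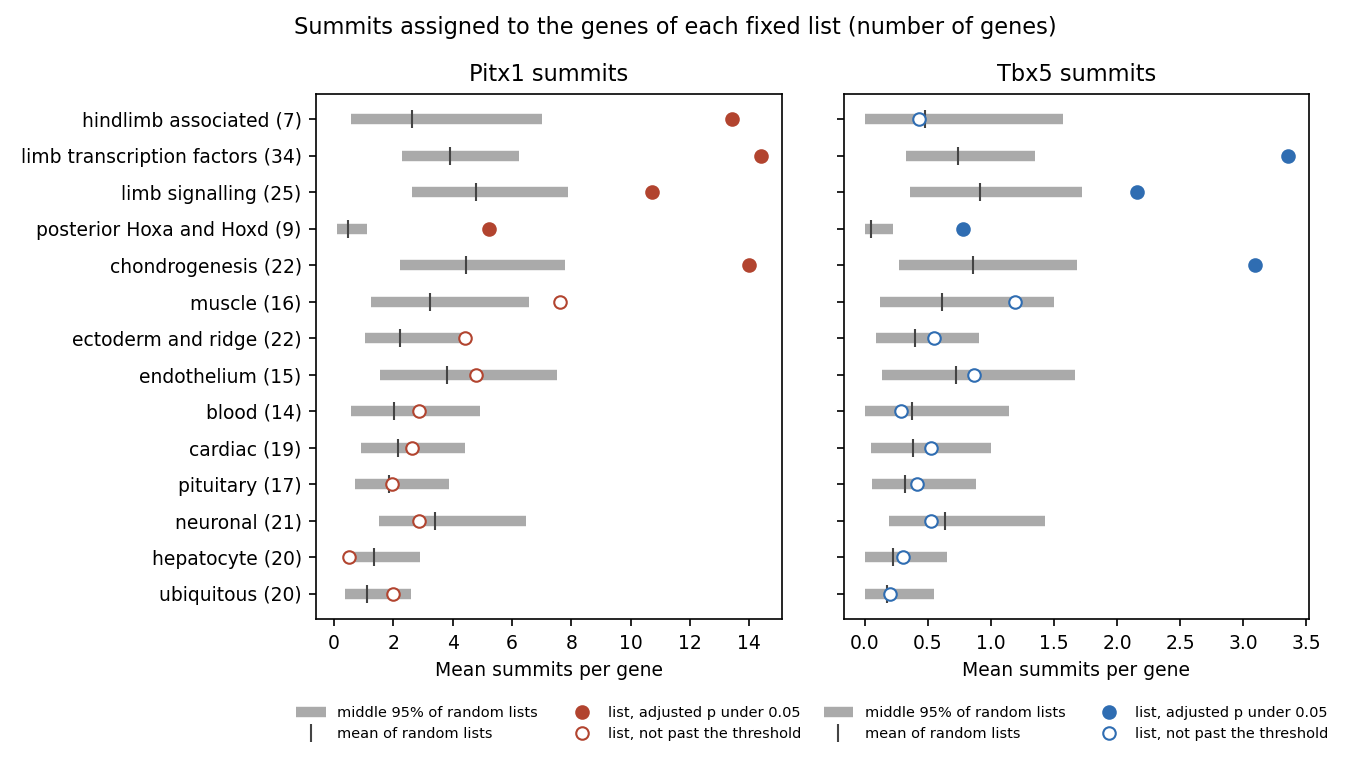
Mean number of summits per gene (horizontal axes) for the 14 tested gene lists (vertical axis, number of genes in brackets), with Pitx1 on the left and Tbx5 on the right. Grey bars span the middle 95% of random lists, ticks mark their mean, and filled points passed the adjusted threshold, 5 lists for Pitx1 and 4 for Tbx5.

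Lists of other cell types did not pass the test for either factor in the main result, which does not set the limb lists apart. No test compared the lists with each other, and the muscle ratio for Pitx1 exceeded the 2.24 of limb signalling. Random lists were matched on domain length alone and drawn from all protein-coding genes. These include families described below, such as odorant receptors, with few summits of either factor. The 16 muscle genes had a mean of 7.63 Pitx1 summits, 2.37 times random (permutation test, adjusted p = 0.0527), with 24 at Mef2c, 22 at Pax3 and 20 at Eya1, and none at the myogenic genes Myod1 and Myog. Their Tbx5 mean was 1.95 times random (permutation test, adjusted p = 0.455). The 22 genes of ectoderm and apical ridge gave 1.97 times random for Pitx1 (permutation test, adjusted p = 0.0768) and 1.38 for Tbx5 (adjusted p = 0.895), with 18 and 2 summits at Dlx6, 12 and none at Sp8, 4 and none at Fgf8 and none of either at Fgf4. For Pitx1, muscle passed under 5 and ectoderm under 4 of 10 alternatives. With the mean of log2 counts, muscle also passed for Tbx5, at 2.09 times random (permutation test, adjusted p = 0.0325, in a range of 0.0325 to 1 over 8 alternatives).

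The remaining lists also stayed short of the threshold in the main result. Pitx1 and Tbx5 ratios were 1.26 and 1.204 for endothelium, 1.422 and 0.769 for blood, 1.22 and 1.37 for cardiac, 1.06 and 1.28 for pituitary, 0.842 and 0.819 for neuronal and 1.83 and 1.12 for ubiquitous genes, the lowest adjusted permutation p among them being 0.220. The ubiquitous list, at 0.220, passed for Pitx1 under 6 of 10 alternatives, at 2.15 to 2.47 times random, with adjusted p from 0.0004 to 0.416 over all 10. Erg and Fli1, transcription factors of endothelium, held 21 and 19 Pitx1 summits, and Runx1, a blood and skeletal regulator, held 22. Nppa and Nppb, cardiac genes that Tbx5 is known to regulate in the heart, had none of either factor. Pomc, a pituitary gene that Pitx1 is known to regulate, had 1 Pitx1 summit with a score of 2.89. The hepatocyte list had the lowest Pitx1 ratio, 0.368 (permutation test, adjusted p = 0.0777), with 10 summits over 20 genes, and a Tbx5 ratio of 1.32 (adjusted p = 0.895). With the mean of log2 counts its Pitx1 ratio was 0.485 and passed (permutation test, adjusted p = 0.0414, in a range of 0.0414 to 0.579 over 10 alternatives).

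No gene list passed the test of a difference between the factors after adjustment. By the permutation test of the log2 difference, 0 of 14 lists passed the adjusted threshold and 1, the hepatocyte list, had an unadjusted p under 0.05 (log2 difference −1.77, p = 0.0058, adjusted p = 0.0812). That list passed when gene domains were extended to their neighbours and when summits were assigned to the nearest gene end. The share of Pitx1 summits that was shared with Tbx5 was 10.02% for limb transcription factors, 10.1% for limb signalling, 8.51% for posterior Hoxa and Hoxd and 11.7% for chondrogenesis, against 7.34%, 7.49%, 4.19% and 7.52% in random lists. None of the 14 lists passed the adjusted threshold for this share in the permutation test, and 1, hepatocyte with 2 of 10 shared, had an unadjusted p under 0.05.

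Chromosome X held few summits in both lists. Pitx1 had 4.73 summits per Mb on X, against 19.0 to 26.7 on the autosomes, and Tbx5 had 27 summits, or 0.158 per Mb, against 3.42 to 4.95. Of the numbered Tbx5 peaks, 4.49% (exact 95% interval 2.98 to 6.47) were present on X, against 54.1% to 78.6% on the autosomes. For Pitx1 the share was 73.4% (70.7 to 76.0) on X, against 75.03% to 80.8%. Without the sex chromosomes, 39.7% of Tbx5 summits were shared with Pitx1, an alternative added after the data were examined.

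**Figure D4:**
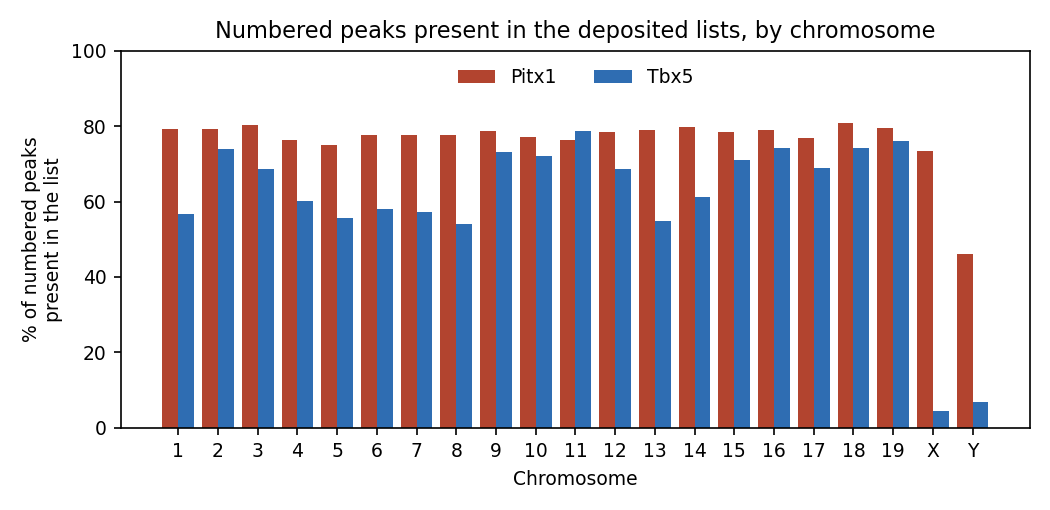
Percentage of numbered peaks that are present in the deposited lists (vertical axis) by chromosome (horizontal axis) for Pitx1 and Tbx5. The Tbx5 bars fall to 4.49% on X and 6.93% on Y.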

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

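Alternatives added after the data were examined are the moved placements, autosomes only, the nearest gene end and 50 classes of domain length. Others were planned. The sharing of sites kept its direction and its side of the threshold under all 10 alternatives, with shared shares from 17.8% to 55.1%, and so did both score trends under 2 alternatives each. Of 60 main values under alternatives, 17 moved beyond a tolerance, which was 1.5 times for a count, the side of the threshold for a test and the exact 95% interval for a share, and 43 did not. Of the values for single lists 206 stayed, 17 came past the threshold, 2 fell short of it and 27 changed direction. No paired analysis was possible because each factor has 1 sample, and no replicate could be left out. Motif alternatives were not run, since no genome sequence was used here. Leaving out summits within 200 bp of a higher one removed none, so values under that alternative could not move. Using autosomes only kept 10225 of the 10273 Tbx5 summits, so it could hardly change the sharing.

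By construction, lists were shorter with the higher-scoring part of each list (27470 Pitx1 and 5136 Tbx5 summits) and with the second Pitx1 list (17783). The share near gene ends changed with the window, to 9.04% for Pitx1 and 5.37% for Tbx5 within 500 bp and to 25.3% and 15.6% within 5 kb. It was 18.3% and 12.1% with the ends of all annotated genes, and 12.8% and 6.52% in the higher-scoring part of each list. For Pitx1 it was 8.80% in the second list and 10.3% at equal length.

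The number of lists past the threshold for Pitx1, 5 in the main result, was 9 with the mean of log2 counts and 8 with 50 classes of domain length, and the 5 lists were among them both times. It was 7 within 1 Mb, with extended domains and with the nearest gene end, 6 within 20 kb and with the share of genes, and 5 under the other 3 alternatives. For Tbx5, 4 in the main result, it was 5 with log2 counts, 3 with the higher-scoring part and 4 under the other 6. The difference between factors, with 0 lists past the threshold, had 1 with extended domains and 1 with the nearest gene end, hepatocyte in both. For these changes the cause was not tested.

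Lists that changed direction against random were all lists not past the threshold in the main result, and for them too the cause was not tested. For Pitx1, the pituitary ratio fell to 0.994 within 1 Mb and 0.753 with extended domains. The neuronal ratio rose to 1.21 with log2 counts and 1.26 with the share of genes, where blood was 0.886. With the higher-scoring part, endothelium was 0.979 and cardiac 0.849. With the second list, cardiac was 0.946 and ectoderm 0.662. At equal length, endothelium was 0.937, cardiac 0.691 and ectoderm 0.578. For Tbx5, the hindlimb ratio was 3.69 within 20 kb, 1.96 within 1 Mb, 2.24 with extended domains, 1.05 with the nearest gene end and 1.32 with 50 classes of length. Blood was 1.07 with extended domains, 1.04 with log2 counts, 1.29 with the share of genes and 1.16 with the nearest gene end. Neuronal was 1.08, 1.36 and 1.04 with log2 counts, the share of genes and the higher-scoring part. Endothelium was 0.878 with extended domains, and ectoderm 0.698 and hepatocyte 0.925 with the higher-scoring part. Read depth is unknown, and the Tbx5 ratios of several lists rest on few summits.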

Other observations

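Tests of chromosome X were chosen after the result was seen, and the gene families and densities were looked at without a plan. Grouping all genes by the stem of their symbol gave 272 families of at least 10 genes. Against random lists, 9 families held more Pitx1 summits and 34 fewer, and 2 held more Tbx5 summits and 5 fewer (permutation test, adjusted over the families). The higher families for Pitx1 were Hoxa at 9.61 times random, Hoxb 6.14, Tcf 3.37, Sp 2.92, Fzd, the Wnt receptors, 2.89, Tbx 2.83, Nkx 2.79, Sox 2.75 and Rpl, the ribosomal protein genes, 2.07. Hoxa, at 16.7, and Hoxb, at 9.69, were the 2 higher families for Tbx5, and each is a single cluster of neighbours, so their p-values are too small. Odorant receptors, with 1110 genes of the stem Olfr, were at 0.0580 for Pitx1 and 0.0593 for Tbx5, and vomeronasal receptors at 0.0505 and 0.0530. Cytochromes P450 were at 0.310 and 0.285. Of the differences between the factors, that of the keratin-associated proteins passed (log2 difference −2.04, adjusted permutation p = 0.0272), and it rests on 9 Pitx1 summits over 56 genes. The secretoglobins also passed, but they hold no summit of either factor and their difference is set by the pseudocount.

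Per 100 kb of assignment domain, in domains of at least 50 kb, the densest for Pitx1 summits included Mrpl23 (26.6), Fzd2 (21.3), Igdcc3 (21.2), Hand2 (20.1), Il17rd (19.9) and Pax9 (19.9), against 2.35 over all genes. These genes were chosen after their values were seen. Tbx5 summits were densest at Rgcc (9.998), Mrpl23 (9.80), Lix1 (7.39) and Ebf3 (5.84), against 0.415 over all genes. Frzb, which encodes a secreted Wnt antagonist of cartilage, was among the 15 densest for both factors, at 18.7 and 5.50.

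The coincidence of Pitx1 and Tbx5 sites was weighed against a pair of technical explanations, with tests chosen after the data were examined but written down before their results were seen. If both lists only crowded into the same broad regions, Tbx5 summits moved by 5 to 20 kb would meet Pitx1 summits as often, yet the highest of 1000 moved sets had 251 shared summits, against 4062. If the coincidence came from protein-coding gene ends, where many antibodies give peaks, it would be missing elsewhere, yet Tbx5 summits over 10 kb from any protein-coding gene end, with ends of other annotated genes not left out, were shared 48.3 times as often as random. Sites of open chromatin that enrich with many antibodies stay open, since the input and histone samples are not analysed here. No biological explanation was tested, and limb, stage and antibody differ together.

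The shortage of summits on X has different values for the factors. Of the numbered Tbx5 peaks on X, 4.49251% were left, below every autosome, in line with removal of X peaks after peak calling. Removal leaves a part unaccounted for, because keeping the autosomal median share of 68.7% would give 2.42 Tbx5 summits per Mb, below the lowest autosome at 3.42. For Pitx1, removal is argued against by 6.45 numbered peaks per Mb on X, below the lowest autosome at 24.4. Copy number in male embryos and the mappability of X were not tested, and no biological explanation was tested.

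The hepatocyte list had a Pitx1 ratio below its Tbx5 ratio. It was asked whether this arises because the Pitx1 list is longer and reaches weaker sites. With lists of equal length the log2 difference was −2.13, within the middle 95% of random lists (−2.33 to 2.31), which met the criterion set before the result was seen. The difference had not shrunk from −1.77 and the range had widened, so this reading was set aside after the value was seen. At equal length 1 Pitx1 summit was left over the 20 genes, so the value is largely set by the pseudocount, and whether list length matters cannot be told.

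The second Pitx1 list holds 32.4% of the longer list, and the share kept rises from 5.35% in the lowest of 10 score classes to 93.7% in the highest. A hypothesis, with its test set before the result was seen, was that at like score the sites shared with Tbx5 are kept more often. Within the 10 score classes, 2380 shared summits were kept, against a mean of 2179 and at most 2280 in random reassignments, a ratio of 1.09 (permutation p = 2e-05, the smallest that 100000 draws can give). The authors marked the second list with a suffix containing "rep2", and it may hold sites matched to a further library, which was not tested. How it was made is not given in the sources used here, and scores still differ within a class.

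Runs of missing peak numbers fall at some of the same places in both lists. On chromosome 8, 72 Pitx1 numbers are missing between positions 20263521 and 20505306, and 209 Tbx5 numbers between 20003314 and 20708617. On chromosome 1, 40 Pitx1 numbers are missing between 85233261 and 85479048, and 196 Tbx5 numbers between 84549716 and 85907120. On chromosome 5, 39 Pitx1 numbers are missing between 15603599 and 15698072, and 254 Tbx5 numbers between 14345272 and 15746986.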
